A study of Homo sapiens with 3 samples.

How the data were processed

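CUT&Tag was made on AC16 cells infected with an Irx3 lentivirus at a multiplicity of infection of 10 with 5 µg/mL polybrene, and libraries were amplified for 14 PCR cycles, per the labels' protocols. Peaks called in each of the 2 Irx3 libraries were used, and the IgG library was not analysed here. Per the submitters' processing notes, the tools were FastQC, cutadapt 2.5, Bowtie2 2.3.5.1, SAMtools 1.9, MACS2 2.2.6 and deepTools 3.4.1, with the build GRCh38. The settings of the peak caller and the handling of duplicates are not given in the sources used here. The deposited peak lists give each peak's fold enrichment, a ratio of pileup to local background at the summit, as the authors' peak caller wrote it. They also hold the authors' −log10 p and −log10 q, a display score the authors' caller derived from them, and the summit's offset. The smallest −log10 q was 1.01 in replicate 1 and 1.00 in replicate 2. Fold values were used to describe, rank or filter peaks and, with p, to recover fragments at the summits.

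Fragments at each summit and the local background were recovered from the fold and the p. The fold was taken as fragments plus 1 over background plus 1, and p as the Poisson probability of more fragments than observed. This gave a whole number of fragments matching −log10 p within 0.001 for 38760 peaks of replicate 1 and 44778 of the peaks of replicate 2. In 18194 simulated peaks, 100.0% of the counts were recovered. Backgrounds under 5 fragments above the floor lay within 0.05 steps of a whole multiple of 0.0155 in both libraries, although depth differed 1.24-fold. Whether the IgG library served as a control is not given in the sources used here. A control scaled to each library's depth would give steps that differ between the libraries. Scaling the libraries to a control would give summit counts that are not whole. The shared step and the whole counts thus argue against the IgG library as a control scaled to depth.

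Peaks on chromosomes 1 to 22 and X were kept. Peaks of both libraries that overlapped by 1 bp or more were joined into shared regions, with the highest fold of each library and the mean of both. Random placement moved each peak or region within its chromosome, over the 1 Mb bins that hold a gene or a peak, 1000 times. Assembly gaps were not used here. Summit counts of the libraries were compared by chi-square outside nuclear copies of mitochondrial genes. In simulated regions with sampling noise alone it was 0.678 to 1.13 per region, and with an added coefficient of variation of 10 percent per library 0.805 to 2.45.

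Genes came from a RefSeq gene table of the same build, GRCh38, from which the copies on alternate sequences were left out. It holds no strand, exons or sequence. The planned promoter, 1 kb either side of the 5′ end, was therefore replaced by 1 kb either side of either end of a gene, so shares include regions at 3′ ends. The planned search for the Iroquois recognition word and 26 motifs, and the split into exons and introns, were not made. Gene lists, 28 in number, were fixed before the data were examined, and 1 member of the calcium list, ORAI1, is not listed as protein-coding and was left out. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. In simulations with no list changed and each gene drawn independently, 2.5% of 200 runs called any list. In the data 7192 of 19839 genes shared an end window with another gene, a dependence that these runs left out. Lists of 20 to 40 genes with a planted share of 80% were called in 45% of 200 runs, and with a planted share of 25% in 27.5%. Departures of this size and smaller can therefore be missed. Each run changed 1 list only, while 16 of the 28 lists were called in the data. The adjustment is stricter when few lists differ, so these runs do not measure the power reached here. Intervals of shares are exact binomial (Clopper-Pearson) and those of fragments exact Poisson, at the 95% level.

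Genes named were those of a rule fixed before the data were examined. They are the 6 Iroquois genes, the 10 genes with the highest mean fold at an end, 16 heart genes, and the 3 members of highest mean fold of each list with a higher share. The 5 distal regions of highest mean fold, over 10 kb from any protein-coding gene end, complete it. The result of 1 heart gene is not reported here. Alternatives were a −log10 q of 5 or more, the 10000 peaks of highest fold per library, reciprocal overlap of 50 percent, summits within 100 bp, every sequence, each library alone, and windows of 500 bp and 2.5 kb. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.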

Results

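The series profiled where the transcription factor Irx3 lies on the genome of AC16 cells after infection with a lentivirus that overexpresses Irx3. AC16 is an established human line made by fusing ventricular heart muscle cells with virus-transformed fibroblasts. Irx3 belongs to the Iroquois homeodomain family, which is known for roles in heart patterning and conduction. The assay was CUT&Tag, in which an antibody brings a transposase to its target and the transposase cuts and tags the DNA nearby. The labels describe 2 libraries made with an Irx3 antibody and 1 made with IgG. Peak lists of the 2 Irx3 libraries were used, and the IgG library was not analysed here. With values of 1 group only, no difference between groups was tested, and no change caused by the overexpression can be read from these values.

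Replicate 1 had 38763 peaks and replicate 2 had 44778 peaks on chromosomes 1 to 22 and X. Median peak width was 630 bp in replicate 1 and 647 bp in replicate 2, and the peaks covered 27.0 Mb and 32.3 Mb. The authors' fold enrichment of a peak over its local background had a median of 5.61 in replicate 1 (quartiles 4.41 and 7.25) and of 5.51 in replicate 2 (quartiles 4.30 and 7.25). Fold enrichment and p together gave the whole number of fragments at each summit, with a median of 15 in replicate 1 and 16 in replicate 2. The lowest background was 0.494 fragments in replicate 1 and 0.614 in replicate 2, a ratio of 1.24.

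Both libraries marked largely the same places, and the strongest regions were found in both. Of the peaks of replicate 1, 83.8% were overlapped by a peak of replicate 2, against 2.28% on average when the peaks of replicate 2 were placed at random. Of the peaks of replicate 2, 72.4% were overlapped, against 1.99% at random. Both shares had a one-sided permutation p of 0.001 over 1000 random placements, the smallest they can give. The overlap made 32239 shared regions with a median width of 847 bp. Agreement followed the number of fragments. In the decile of peaks with the fewest fragments, 37.5% were overlapped in replicate 1 and 18.2% in replicate 2, and in the decile with the most the shares were 99.9% and 99.7%. Across shared regions, which are not independent replicates, Spearman's rho of the fold enrichment was 0.772 (95% bootstrap interval over regions 0.767 to 0.777).

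**Figure D1:**
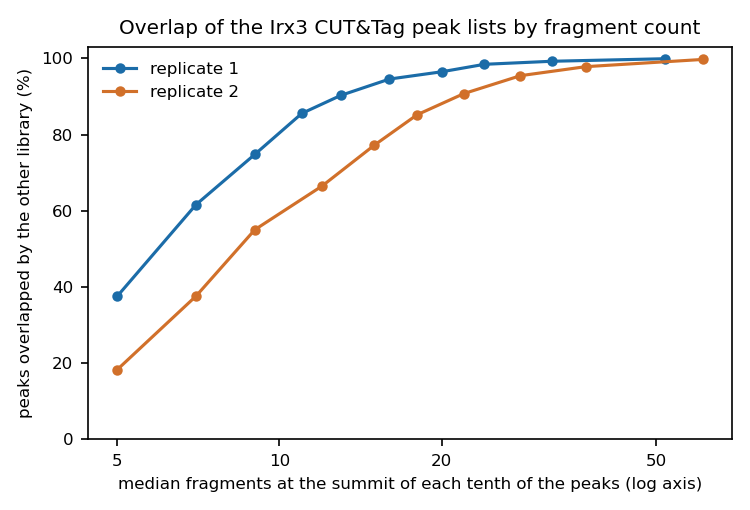
Percent of peaks overlapped by the other library (y axis) against the median number of fragments at the summit (x axis, log scale), for deciles of the peaks of replicate 1 (blue) and replicate 2 (orange). The share rises from 37.5% to 99.9% in replicate 1 and from 18.2% to 99.7% in replicate 2.

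Summit fragments of the 2 libraries were compared at 10080 shared regions with summits within 100 bp and at least 40 fragments in sum, without regions over nuclear copies of mitochondrial genes. At these regions, which were selected for close summits, no difference beyond sampling noise was detected region by region. The chi-square was 0.757 per degree of freedom around a common ratio of 1.24, against 0.678 to 1.13 in simulations of sampling noise alone. At the 290 of them with at least 200 fragments in sum the chi-square was 0.991 per degree of freedom. That value also lies in the range simulated with an added variation of 10 percent per library (0.805 to 2.45). The 0.757 of all 10080 regions lies below that range. The simulated ranges pool region shapes and fragment numbers that were matched to neither set. Nor were the simulated regions selected for close summits. The simulations therefore cannot decide whether a difference of that size is present. The 2 libraries were counted as 1 sample, which their agreement alone does not establish. Each library's own value is given, and no mean with SD is used. The ratio of replicate 2 to replicate 1 did differ between chromosomes, from 1.19 on the X chromosome to 1.31 on chromosome 21 (permutation p = 2e-05 over 100000 permutations of regions). Nothing in the labels says that the libraries came from separate cultures, so agreement between them measures only the spread between these libraries.

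Shared regions gathered at the ends of protein-coding genes. Within 1 kb of such an end lay 28.2% of the shared regions, 7.33 times the 3.85% of randomly placed regions (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Another 38.4% lay inside protein-coding genes (42.4% at random) and 33.4% outside them (53.7% at random), each lower than in every random placement. Gene ends were assigned first, so the excess there by itself lowers both of these shares. Away from gene ends, more regions lay inside genes than outside them, while random placement gave the reverse. Among the 1000 regions of highest mean fold, 40.2% lay at gene ends. The share was 25.3% for the peaks of replicate 1 alone and 23.4% for those of replicate 2 alone. In all, 10182 of 19839 protein-coding genes (51.3%) had a shared region within 1 kb of an end. Among the 14262 genes longer than 10 kb, 7499 had a region at 1 end and 475 at both, where independent ends would give 1251 genes with both (odds ratio 0.212, Fisher's exact test, two-sided p = 7.07e-240). The gene table used here gives no strand, so the 5′ end could not be told from the 3′ end.

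Genes of ribosomal proteins, oxidative phosphorylation and the unfolded protein response carried regions most often among the lists. Of 78 genes of cytosolic ribosomal proteins, 70 had a region (89.7%, 95% exact binomial interval 80.8 to 95.5), as did 67 of 76 genes of oxidative phosphorylation (88.2%, 78.7 to 94.4). The unfolded protein response, which adjusts the folding capacity of the endoplasmic reticulum, had 20 of 22 genes with a region (90.9%), autophagy and lysosome 23 of 27 (85.2%), and apoptosis and p53 targets 21 of 25 (84.0%). Ferroptosis and redox had 20 of 24 (83.3%), cell cycle and DNA replication 33 of 40 (82.5%), and inflammation and NF-kB 18 of 24 (75%). These 8 of the 28 gene lists passed Fisher's exact test (two-sided, Benjamini-Hochberg over the lists) with a share above that of all other protein-coding genes. The adjusted p ranged from 7.38e-12 for ribosomal proteins to 0.0474 for inflammation and NF-kB. The inflammation call ended with a −log10 q of 5 or more, with replicate 2 alone, with the 2.5 kb window and with summits within 100 bp (adjusted p = 0.654, 0.136, 0.0999 and 0.628, Fisher's exact test), and the apoptosis call ended in the stricter q setting (0.0722). With summits within 100 bp the calls of apoptosis, cell cycle, autophagy, ferroptosis and the unfolded protein response also ended (0.0814, 0.172, 0.331, 0.109 and 0.0714, Fisher's exact test), and ribosomal proteins and oxidative phosphorylation alone stayed above. Odds ratios ran from 2.85 for inflammation to 9.50 for the unfolded protein response.

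Within these lists the folds of the strongest members were close to each other in the 2 libraries. A region was credited to every gene with an end within 1 kb, so a fold can belong to a neighbouring gene or a 3′ end. At CDK2, for example, the region (55973197 to 55974439 on chromosome 12) lay wholly beyond the gene's upper end at 55972789. RPS19, a component of the small ribosomal subunit, had a fold of 12.3 in replicate 1 and 15.1 in replicate 2. RPL28 reached 11.7 and 13.6, and RPS9 13.1 and 11.5. In oxidative phosphorylation, COXFA4 (listed under its older symbol NDUFA4) had folds of 15.0 and 12.6, the complex I subunit NDUFA11 13.6 and 13.4, and the ATP synthase subunit gene ATP5MC1 13.1 and 12.3. Replication and division genes were led by CDC45, part of the replicative helicase (12.9 and 12.9), the kinase CDK2 (12.9 and 12) and CCNB2, a B-type cyclin (11.4 and 10.6). ATG3 (14.3 and 14.3), ATG10 (10.5 and 11.5) and ATG12 (9.93 and 9.76), all of the autophagy conjugation machinery, led their list. PDIA4, a disulfide isomerase of the endoplasmic reticulum, had folds of 14.3 and 13.8, the stress sensor kinase EIF2AK3 13.3 and 13.3, and SEL1L 9.52 and 10.9. The cell death genes DIABLO (11.4 and 13.1), CYCS (10.6 and 10.8) and APAF1 (9.41 and 8.62) led the apoptosis list, and the ferroptosis list was led by the redox and lipid genes LPCAT3 (13.4 and 11), NQO1 (11.7 and 11.6) and SOD2 (10.2 and 10.6). In the inflammation list NFKBIB, an inhibitor of NF-kB, had folds of 12.7 and 11.4, RELB 7.85 and 7.11, and TNFAIP3 6.99 and 7.74. CDC45, CCNB2, SEL1L and TNFAIP3 had no shared region at an end with summits within 100 bp, RELB and TNFAIP3 none with the 10000 peaks of highest fold per library, and DIABLO none with the 500 bp window.

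Olfactory receptors, endothelial markers and cardiac ion channels carried regions least often among the lists. Among the heart lists, cardiac ion channels and gap junctions had 4 of 28 genes with a region (14.3%, 95% exact binomial interval 4.03 to 32.7) and cardiac sarcomere and contractile genes 7 of 25 (28.0%, 12.1 to 49.4). Of 387 olfactory receptor genes, 6 had a region (1.55%), and shares were as low as 12.5% for endothelial (2 of 16), 16.7% for leukocyte (3 of 18), 18.8% for hepatocyte (3 of 16) and 23.5% for neuron markers (4 of 17). The HOX clusters, homeodomain genes of body patterning, had 12 of 39 (30.8%). Among them HOXC4, HOXC5 and HOXC6 had identical folds (6.24 in replicate 1 and 5.51 in replicate 2), as from the same region. All 8 lists were below the other protein-coding genes by Fisher's exact test, with an adjusted p from 4.05e-109 for olfactory receptors to 0.0479 for the sarcomere and neuron lists and 0.000424 for ion channels. Against random lists of matched gene length, chosen after seeing the data, the sarcomere, HOX, hepatocyte and neuron calls ended (adjusted p = 0.0540, 0.195, 0.0635 and 0.0508 by permutation). The matched lists had mean shares of 51.7%, 43.5%, 48.1% and 53.2%. Matching thus lowered the expected share clearly only for HOX, and the gap of the other lists stayed about as wide. The sarcomere call also ended with a −log10 q of 5 or more (0.236, Fisher's exact test), with the 2.5 kb window (0.0999, the same test) and with summits within 100 bp. The HOX call ended in each library alone (0.0533 and 0.118, Fisher's exact test) and without genes sharing a window. The ion channel call ended with summits within 100 bp (0.0814, Fisher's exact test). The neuron call ended with reciprocal overlap (0.134), with the 2.5 kb window (0.0829) and without genes sharing a window (0.192), and the hepatocyte call with the 2.5 kb window, where the share was 43.8% (0.468), without genes sharing a window (0.0521) and with summits within 100 bp (0.111), by the same exact test. With summits within 100 bp only olfactory receptors and neuron markers stayed below. With only the 10000 peaks of highest fold per library, olfactory receptors and HOX clusters alone stayed below and ribosomal proteins and oxidative phosphorylation alone stayed above.

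**Figure D2:**
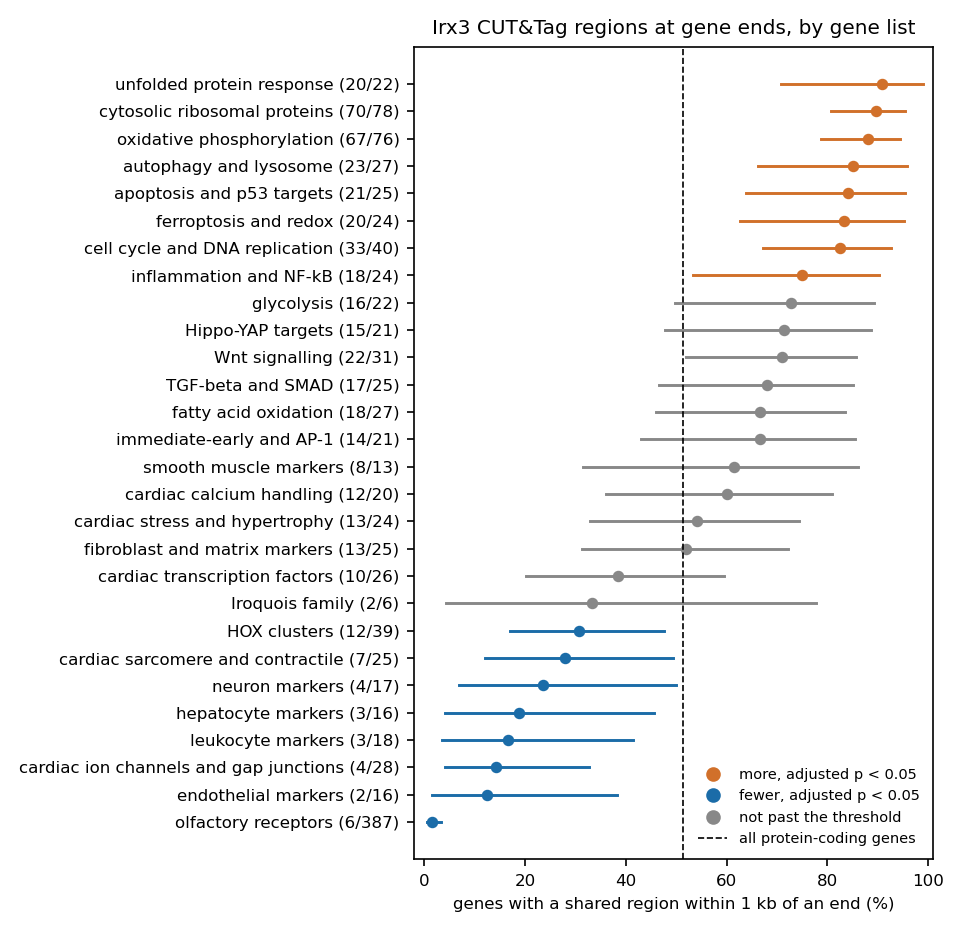
Percent of the genes of each list with a shared region within 1 kb of an end (x axis, points) with 95% exact binomial intervals (lines), with members with a region and all members in brackets. Lists above the other protein-coding genes are orange, lists below are blue and the rest are grey, and the dashed line marks the 51.3% of all protein-coding genes.

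The other 12 lists did not pass the test. Cardiac calcium handling had 12 of 20 genes with a region, cardiac stress and hypertrophy 13 of 24, cardiac transcription factors 10 of 26, and the Iroquois family 2 of 6. Fibroblast and matrix markers had 13 of 25 and smooth muscle markers 8 of 13. Glycolysis had 16 of 22, fatty acid oxidation 18 of 27, immediate-early and AP-1 genes 14 of 21, Hippo-YAP targets 15 of 21, TGF-beta and SMAD 17 of 25, and Wnt signalling 22 of 31. Their adjusted p ranged from 0.0512 to 1 (Fisher's exact test). Some passed with a higher share under alternatives: glycolysis with a −log10 q of 5 or more and in each library alone, fatty acid oxidation and Hippo-YAP targets in replicate 2 alone, and immediate-early genes with the 2.5 kb window. Without genes sharing a window, immediate-early, Hippo-YAP, TGF-beta and Wnt genes passed.

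Among the heart genes named in advance, TNNT2, KCNJ2 and NPPB had a shared region at an end. TNNT2, the cardiac troponin T gene, had folds of 8.55 in replicate 1 and 10.0 in replicate 2. At KCNJ2, which encodes an inward rectifier potassium channel, the folds were 9.43 and 7.27, from 22 and 20 fragments. NPPB, the B-type natriuretic peptide gene, had folds of 5.67 and 6.39. No shared region lay within 1 kb of an end of the connexin genes GJA1 and GJA5, the channel gene KCND2, the peptide gene NPPA, or the contractile genes MYH6, MYH7 and ACTC1. The heart regulators GATA4, NKX2-5, TBX5, HAND2 and MEF2C had none either. TNNT2 had none within 500 bp of an end, and KCNJ2 and NPPB had none when only the 10000 peaks of highest fold per library were kept. GATA4 had a shared region within 2.5 kb of an end.

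**Figure D3:**
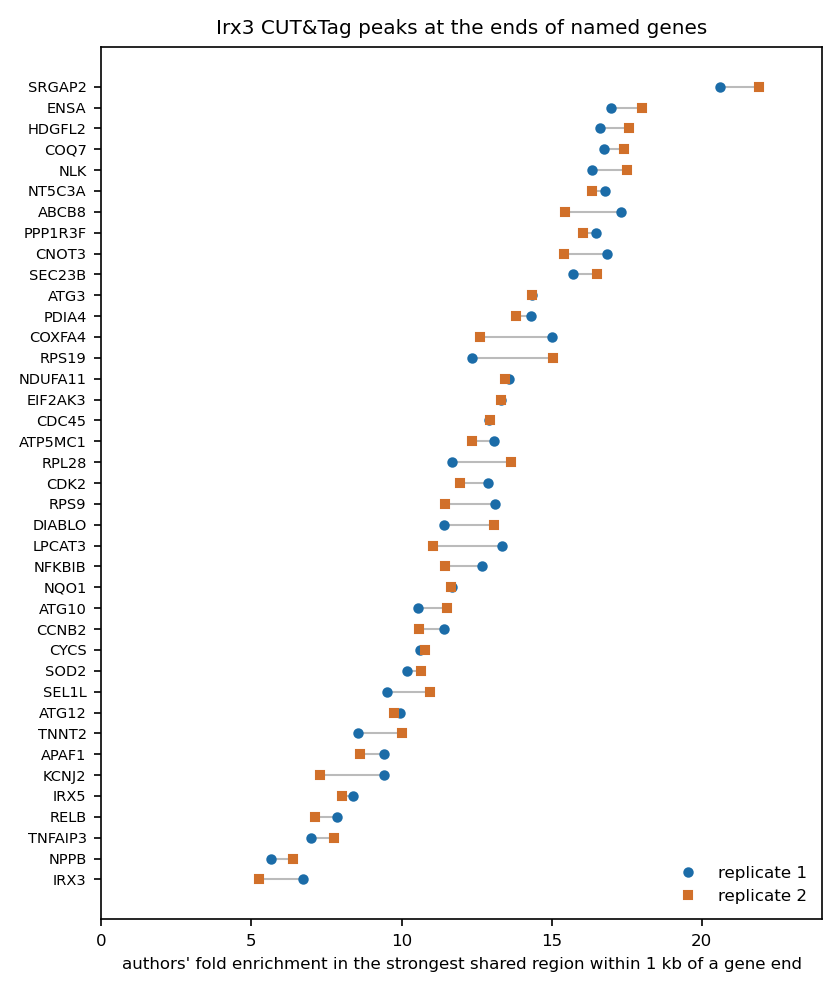
The authors' fold enrichment (x axis) in the strongest shared region within 1 kb of an end of each named gene that has one (y axis), in replicate 1 (blue circles) and replicate 2 (orange squares), with a grey line between them. SRGAP2 is highest, at 20.6 and 21.9, and IRX3 has the lowest mean, from 6.72 and 5.24.

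IRX3 itself carried a broad region of moderate fold. It spanned positions 54284589 to 54287074 on chromosome 16 (GRCh38) and covered 63.1% of the gene, which lies at 54283304 to 54286787, including its upper end. Folds were 6.72 in replicate 1 and 5.24 in replicate 2, from 39 fragments (95% exact Poisson interval 27.7 to 53.3) and 37 fragments (26.1 to 51.0). At 2486 bp it was wider than 99.8% of the shared regions, while 46.9% of them had a lower mean fold, and its summits lay 891 bp apart in the 2 libraries. The infected cells carry a viral copy of Irx3 as well, and fragments of the gene and of the virus were not told apart here. IRX5, a neighbour in the same cluster, had a region at 54928935 to 54930218, 647 bp from its lower end at 54930865. Its folds were 8.38 and 8.03, from 52 fragments (38.8 to 68.2) and 60 fragments (45.8 to 77.2), though the peak of replicate 1 alone ended 1012 bp from the gene. IRX1, IRX2, IRX4 and IRX6 had no shared region at an end. Poisson intervals cover counting error only.

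**Figure D4:**
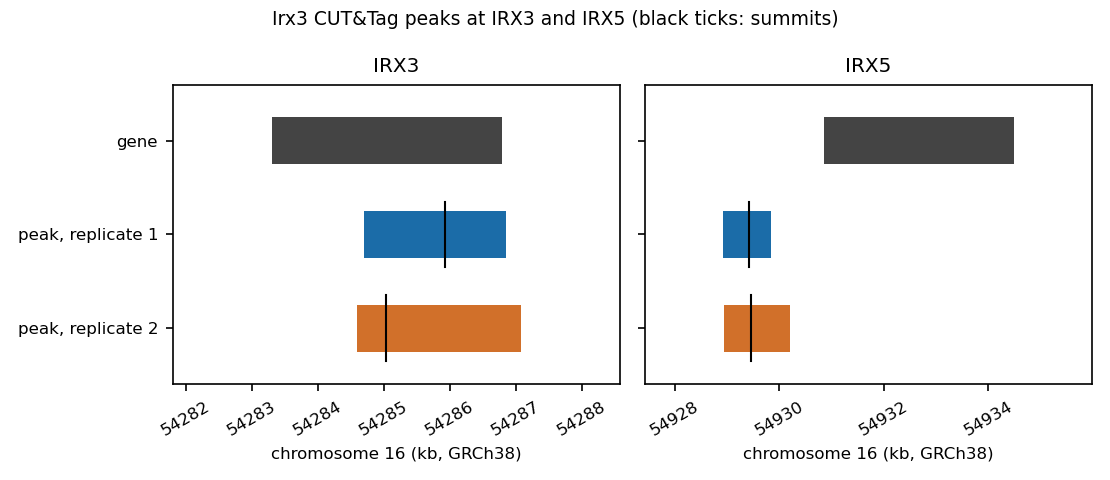
Maps of chromosome 16 (x axis, kb, GRCh38) at IRX3 (left) and IRX5 (right), with the gene in grey, the peak of replicate 1 in blue, the peak of replicate 2 in orange and the summits as black lines. The peaks at IRX3 cover most of the gene, and those at IRX5 lie outside it, 1012 bp and 647 bp from its lower end.

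The highest folds at gene ends were found near genes of varied function. SRGAP2, a regulator of cell shape and migration, led with folds of 20.6 in replicate 1 and 21.9 in replicate 2. ENSA, an inhibitor of a mitotic phosphatase, followed with 17.0 and 18.0, and HDGFL2 with 16.6 and 17.6. COQ7, an enzyme of ubiquinone synthesis, had 16.7 and 17.4, the kinase NLK 16.4 and 17.5, and the nucleotidase NT5C3A 16.8 and 16.3. The mitochondrial transporter ABCB8 had 17.3 and 15.5, PPP1R3F 16.5 and 16, CNOT3 of the deadenylase complex 16.8 and 15.4, and SEC23B of the vesicle coat 15.7 and 16.5. NLK had no shared region within 500 bp of an end.

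Far from gene ends, 18096 shared regions (56.1%) lay over 10 kb from any protein-coding gene end, and 51.7% of these were inside a protein-coding gene. The 2 with the highest mean fold lay over nuclear copies of mitochondrial genes. A region at 53105733 to 53106482 on chromosome 17, over the pseudogene MTCO1P40, had folds of 22.3 and 22.9, and its nearest protein-coding gene was KIF2B, 716 kb away. A region at 100050485 to 100051532 on chromosome 5, over MTND4LP5, MTND3P19 and MTCO3P22, had folds of 19.2 and 19.4. Next came a region at 29258562 to 29259365 on chromosome 21, inside the non-coding gene LINC00189 and 39.6 kb from BACH1, with folds of 16.7 and 17.4. A region at 114933468 to 114934130 on chromosome 12, 249 kb from the heart regulator gene TBX3, had folds of 16.6 and 17.3. The last, at 39213221 to 39214011 on chromosome 15, had folds of 15.7 and 17.3 and lay 366 kb from the nearest protein-coding gene end.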

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

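Added after seeing the data were random lists matched on gene length, leaving out genes that share an end window with another gene, leaving out nuclear copies of mitochondrial genes, and a minimum of 20 fragments. The overlap of the libraries and the excess of regions at gene ends kept a permutation p of 0.001 under every alternative run, with 43.7% to 81.6% of peaks overlapped and 23.4% to 39.1% of regions at gene ends. The excess over random placement ran from 4.35 times with the 2.5 kb window, where 7.31% was reached at random, to 10.0 times with the 500 bp window. Shared regions fell to 7253 with the 10000 peaks of highest fold per library and to 18247 with summits within 100 bp, since both take fewer peaks as shared. Spearman's rho was 0.762 with a −log10 q of 5 or more, 0.602 with the 10000 highest peaks, 0.777 with reciprocal overlap and 0.801 with summits within 100 bp. Lists with more regions were 2 with the 10000 highest peaks and 2 with summits within 100 bp, and between 7 and 12 otherwise. Lists with fewer regions were 2 and 2 under the same settings, 5 with the 2.5 kb window, 5 without genes sharing a window and 4 with length matching, and 7 or 8 otherwise. The cause was not tested. With the 10000 highest peaks the share of the inflammation list was 4.17%, below that of the other genes but not past the threshold (adjusted p = 0.411, Fisher's exact test). That setting left 7253 shared regions in place of 32239, so fewer genes of any kind can carry one. The 4.17% is therefore not comparable with the 75% of the main setting. IRX3 had no shared region with the 10000 highest peaks or with summits within 100 bp. IRX5 had none with the 500 bp window or in replicate 1 alone. Of the 76 alternatives listed before the data were examined, 39 were not run: those of motifs, of transcript 5′ ends and of GC-matched lists need sequence or transcripts that were not used here. No paired analysis was possible because only 1 group was analysed here.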

Other observations

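The tests of families, of other kinds of genes, of FTO, of length-matched lists, of isolated tRNA genes, of nuclear copies and of the split over chromosomes were chosen after the results they follow up were seen, and only the bounds for the pooled length test were set before that test was run. Protein-coding families sharing a symbol root of at least 20 genes also differed, with 29 of 102 families above and 28 below the other genes (Fisher's exact test, two-sided, adjusted p under 0.05). Mitochondrial ribosomal proteins carried regions at 27 of 28 MRPS and 42 of 49 MRPL genes. Centrosomal CEP genes had 35 of 39, vacuolar sorting VPS genes 31 of 35, Mediator MED genes 26 of 30, and RNA polymerase POLR genes 28 of 33. Zinc finger ZNF genes, the most numerous, had 323 of 517 (62.5%). Keratin-associated KRTAP genes had 3 of 94, keratins (KRT) 5 of 55, beta-defensins (DEFB) 0 of 39, UGT detoxifying enzymes 0 of 22, cytochrome P450 (CYP) genes 10 of 56, and tight junction claudins (CLDN) 1 of 24. Genes with the symbol roots CCL (2 of 26) and IL (29 of 85) were below. The inflammation list, which was above, holds only some of their members. The COX (18 of 26) and ATP (53 of 86) families did not pass.

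Among genes of other kinds, 178 of 431 tRNA genes (41.3%, 95% exact binomial interval 36.6 to 46.1) had a shared region within 1 kb of an end. Long non-coding RNA genes had 3757 of 17950 (20.9%), snRNA genes 37 of 152 (24.3%), miRNA genes 198 of 1911 (10.4%) and snoRNA genes 90 of 1191 (7.56%). Pseudogenes had 443 of 15096 (2.93%), and transcribed pseudogenes, which are listed apart, 166 of 1230 (13.5%). Over 10 kb from any protein-coding gene end the shares were lower, at 10.3% for long non-coding RNA, 13.9% for snRNA, 3.96% for miRNA and 3.56% for snoRNA genes. FTO, the neighbour of IRX3 known for variants tied to body mass, was looked at after its values were seen. It held 6 shared regions over 418 kb, or 1.44 per 100 kb, against a median of 0.973 for 3350 genes over 100 kb, and 61.4% of those had fewer. Between IRX3 and IRX5, besides the region near IRX5, lay 2 shared regions, with mean folds of 7.02 and 7.30.

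Of the 28 gene lists, 8 had more and 8 fewer genes with a region than the other genes, and whether this follows breadth of expression was not tested. Against length-matched random lists, 75% of the called lists (12 of 16, 95% exact binomial interval 47.6 to 92.7) stayed past the threshold. This equals the bound of 75% set beforehand for leaving out gene length. The demand that the interval clear that bound was added after the value was seen, so by that rule gene length stays undecided for the pooled lists. All 8 lists with more regions stayed (100%), which argues against gene length for those, and 4 of the 8 with fewer did not stay. For the sarcomere, hepatocyte and neuron lists, the 95% exact binomial intervals of the shares ended at 49.4%, 45.6% and 49.9%. These leave out the matched mean shares of 51.7%, 48.1% and 53.2%, but narrowly, and the intervals were not adjusted over the lists. The adjusted permutation test against matched lists called none of them (0.0540, 0.0635 and 0.0508). The matched means show that gene length moved the expected shares little, while the gap that remains was not past the threshold. For HOX the interval (17.0 to 47.6) holds the matched mean of 43.5%, so gene length stays open there. Cutting of open chromatin unrelated to the antibody's target stays open: of tRNA genes over 10 kb from any protein-coding gene end, which another polymerase reads, 76 of 279 (27.2%) had a region, against 71 of 1869 snoRNA and miRNA genes as far away (3.80%; odds ratio 9.48, Fisher's exact test, two-sided p = 1.43e-32), but the shares of all these genes had been seen before and binding of Irx3 at open sites would give the same. Base composition and binding of Irx3 itself stay open as well, the IgG library was not analysed here, and no biological explanation was tested.

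The 5 regions with the most fragments in replicate 1 lay over nuclear copies of mitochondrial genes, led by 629088 to 631005 on chromosome 1 with 7748 fragments in replicate 1 and 7774 in replicate 2. Mitochondrial fragments placed on these copies are a candidate explanation. At the 14 regions over such copies replicate 2 had 0.998 times the fragments of replicate 1 (95% exact binomial interval 0.979 to 1.02), against 1.24 at other regions. The latter were 10080 regions with summits within 100 bp and at least 40 fragments in sum, a filter not set for the copies. The 5 largest copies set the 0.998, since the other 9 held only 379 of the 19316 fragments in replicate 1. Loss of fragments to duplicate removal at very high coverage was not borne out, since the 9 copies with under 200 fragments had a ratio of 1.02 (0.884 to 1.18, counting error only), which leaves out 1.24, as does the 95% t interval with each copy as 1 value (0.864 to 1.21). A nuclear source that differs between the libraries stays open, and no biological explanation was tested.

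Region by region, at regions with close summits outside nuclear copies of mitochondrial genes, no difference beyond sampling noise was detected between the 2 libraries. Their ratio of summit fragments still differed between chromosomes, and it was 0.998 at those copies against 1.24 elsewhere. Sequencing of 1 library again with equal composition was not borne out, since the split between libraries differed between chromosomes (permutation p = 2e-05). The ratio of replicate 2 to replicate 1 was 1.23 at gene ends and 1.24 elsewhere. Separate reactions on 1 pool of cells, or 1 reaction amplified or sequenced with different bias, stay open, and no biological explanation was tested.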
